A study of Homo sapiens with 4 samples.

How the data were processed

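RNA was measured in LS180 cells, an established human colon carcinoma line, with a Tet-off system in which withdrawing doxycycline switches on RBM35A. RBM35A is the older name of ESRP1, an RNA-binding protein of epithelial cells that regulates splicing. RBM35A+ cells had been without doxycycline for at least 6 days. RBM35A− cells were kept with doxycycline; the labels call them parental and do not say whether they carried the RBM35A construct. From each state, total RNA was extracted with TRIZOL, and polysomal RNA, the RNA on transcripts loaded with several ribosomes, was isolated on sucrose gradients. The labels give polyA RNA as the molecule of the polysomal arrays and total RNA as that of the others, while their protocols describe no poly(A) selection. Per the labels' protocols, 10 µg of RNA per sample was converted to biotinylated cRNA and hybridized to Affymetrix HG-U95Av2 arrays, which read short probes that lie mostly toward the 3′ end of transcripts. There were 4 arrays, 1 for each combination of RBM35A state and RNA fraction, with no replicates. Doxycycline and RBM35A changed together on every array, as did the cell line if the parental cells lacked the construct. RNA fraction changed together with the extraction method and with any poly(A) selection. These could not be separated.

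The deposited values are on a log2 scale and were made by the authors with GCRMA, per the submitters' processing notes; its version was not given in the sources used here. GCRMA corrects the background of each probe from its base composition and summarises the probes of a set. Sorted values of the 2 total RNA arrays differed by at most 4.29e-06 and those of the 2 polysomal arrays by at most 6.61e-06, while the distributions of the fractions differed by up to 0.227. Each pair had thus been quantile normalized within the pair and apart from the other pair. A shift that covered most genes of 1 array of a pair would have been removed by this step, and levels compared across fractions rest on separately normalized arrays.

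Each array held 12626 probe sets, of which 67 were controls. The array annotation gave 10943 probe sets 1 gene symbol, 546 several and 1070 none. Of those with 1 symbol, 10934 were matched by gene ID to a current symbol in a RefSeq gene table of assembly GRCh38.p14 and 9 kept the symbol of the annotation; the table was used for names only, and no coordinates are given because the array data name no genome build. Probe sets with no or several symbols and the controls were left out of gene results. Each of the 8225 genes was represented by its probe set with the highest mean over the 4 arrays. Values under a floor of 5 (log2) were raised to 5, and the 3588 genes at 5 or more on at least 1 array were analysed. A difference with 1 floored value is a lower bound in size. Where both values were floored the difference reads 0 but is unknown, and a difference of differences with such a pair rests on the other fraction alone and bounds nothing. Probe sets that can hybridize with near-identical family members, such as those of the metallothioneins, ribosomal proteins, CYP3A5, DDX11 and LGALS9, are uncertain as to gene.

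Before the data were examined, the comparisons, the gene lists, the other settings to try and the rule for named genes were fixed. Log2 differences between RBM35A+ and RBM35A− were taken within total RNA and within polysomal RNA, with genes counted at 2-fold, and the difference between these differences was taken per gene at a size of 1 (log2). None of these has a p-value, since each group had 1 array. As a measure of error, the SD of 1 probe set's difference was estimated from the disagreement between probe sets of the 358 genes with at least 2 measured ones: 0.185 in total RNA, 0.18 in polysomal RNA, 0.23 for the difference of differences and 0.706 for polysomal minus total RNA. This covers differences between probes and not those between cultures. An additive model of RBM35A state and fraction was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes analysed and a threshold of 0.05. It left 1 residual degree of freedom, which holds the interaction of state and fraction, so its p-values measure whether an effect was alike on both levels of the other factor and not whether it would recur in other cultures.

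For each of 32 gene lists (pathways, complexes and cell type markers), the median difference of the analysed members was placed among 10000 random lists of the same size, each member replaced by a random one of the 100 genes outside the list nearest in mean level. A list outside the central 95% is said to stand apart. This describes these arrays and is no test. Lists needed at least 3 analysed members, and members were counted at 1.5-fold. With 29 lists in 4 comparisons, 5.8 of the 116 medians were expected outside the band by chance if list members vary independently. Members that vary together would raise this number. The 116 medians are also not separate, since the difference of differences is built from the 2 others and some lists share members. The named genes are the 8 highest and 8 lowest in each fraction and in the difference of differences, the 12 highest and 12 lowest by the smaller of the 2 differences for both fractions together, the 10 with the largest mean difference per direction past the threshold for fraction, the 5 with the smallest p per direction where none passed, and up to 4 members per list with the largest difference.

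The other settings were floors of 4 and 6, no floor, centring of each array on its median, cyclic loess, quantile normalization of all 4 arrays, the mean of a gene's probe sets, removal of probe sets whose suffix marks shared sequence, and limma with an intensity trend or robust variance. Removal of a linear trend of the RBM35A differences on the polysomal minus total difference was added after the data were seen. The limma step was tested on 20 simulated data sets of 3588 genes for the shared RBM35A effect: a change of 1 (log2) was called in a median of 99% of changed genes (92 to 100) and a change of 0.5 in 36% (5 to 86), and unchanged genes made up a median of 6.83% of calls (0 to 20.5). These simulations drew independent noise from the variances that limma had fitted, without a floor. They changed 100 genes per size, equally in both fractions. The rates therefore do not cover genes whose change differs by fraction, such as CYP3A5, which was not called at a mean difference of 1.15. In simulated lists for total RNA over 3388 genes, a shift of 0.2 in 20 genes lay at percentile 100, and 6% of 200 unchanged lists lay outside the band. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. For arrays, precision is limited by their number.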

Results

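Transcript levels were measured on 4 arrays of LS180 colon carcinoma cells: total RNA from RBM35A− and RBM35A+ cells, and polysomal RNA from RBM35A− and RBM35A+ cells, with 1 array each. The study asked how expression of RBM35A alters total and polysomal mRNA. On each total RNA array 4269 of 12626 probe sets (33.8%) reached a log2 value of 5, and on each polysomal array 4312 (34.2%) did. The correlation across probe sets was 0.998 between the total RNA arrays, 0.999 between the polysomal arrays, and 0.963 to 0.969 between arrays of different fractions. All differences are log2 values, and the differences between RBM35A+ and RBM35A− cells have no replicate check.

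No probe set (0) was annotated to RBM35A itself, so the state of the cells rests on the labels, which do not say whether the RBM35A− cells, called parental, carried the construct. Markers of cells other than epithelium were mostly undetected: of 17 haematopoietic markers on the array 1 was analysed, HBB, with differences of 0.03 in total and 0.04 in polysomal RNA, and of 17 fibroblast and endothelial markers 1 was analysed, COL1A1, at the floor on both total RNA arrays and with 0.02 in polysomal RNA. Of the nuclear-retained and non-coding RNAs, 1 of 2 on the array was analysed, TUG1, with 0.09 and 0.29.

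Control probe sets lie at the 5′ end, in the middle and at the 3′ end of the beta-actin and GAPDH transcripts. The beta-actin 5′ probe set read 14.79 and 14.75 in total RNA of RBM35A− and RBM35A+ cells, but 10.29 and 9.42 in polysomal RNA, whereas its 3′ probe set read 14.25, 14.20, 13.95 and 13.93. The mean polysomal minus total difference was −4.91 at the 5′ end and −0.29 at the 3′ end. For GAPDH, the polysomal minus total difference was −2.21 at the 5′ probe set, −1.31 in the middle and −0.15 at the 3′ probe set. The polysomal arrays also differed from each other at the 5′ ends: RBM35A+ minus RBM35A− was −0.86 for beta-actin and −0.79 for GAPDH, against −0.02 and −0.13 at the 3′ ends. In total RNA the same 5′ probe sets differed by −0.05 and −0.03. The transferrin receptor control read 8.55 and 8.99 at its 3′ probe set and 6.16 and 6.60 at its 5′ probe set in total RNA, and lay below the floor at both in polysomal RNA. Where along its transcript each gene's probe set lies was not used here.

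**Figure D1:**
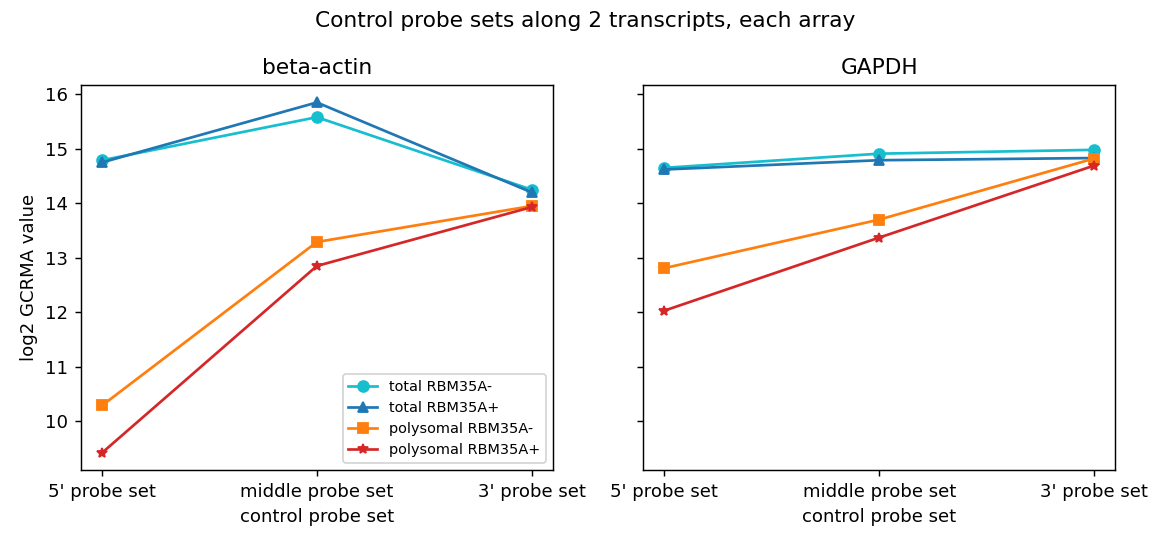
Log2 GCRMA values (y axis) of the 5′, middle and 3′ control probe sets (x axis) of beta-actin and GAPDH on each of the 4 arrays, 1 marker and line per array. The polysomal arrays lie below the total RNA arrays at the 5′ end, at 10.29 and 9.42 against 14.79 and 14.75 for beta-actin, and near them at the 3′ end.

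In total RNA, 5 genes were at least 2-fold higher in RBM35A+ than in RBM35A− cells and 0 were at least 2-fold lower. CYP3A5, a drug-metabolizing cytochrome P450 of liver and gut, was 3.32-fold higher (5.41 to 7.14). MUC2, the main secreted mucin of intestinal goblet cells, was 2.75-fold higher (6.54 to 8.00), and MAPRE3, which binds the growing ends of microtubules, was 2.64-fold higher (6.23 to 7.63). NISCH, an integrin-binding protein, was 2.18-fold higher (5.06 to 6.18). GAS6, a ligand of the TAM receptor tyrosine kinases, was at least 2.01-fold higher, but its 2 other measured probe sets gave −0.25 and 0.07. The next highest genes were the deubiquitinase USP11 (0.90), the DNA helicase DDX11 (0.89) and the galectin LGALS9 (0.88, other probe set at the floor). In RBM35A+ cells the polysomal minus total difference of the 5 genes higher by 2-fold was between 1.42 for CYP3A5 and 4.05 for GAS6. The Alu repeat control was 0.38 higher in total RNA of RBM35A+ cells, and 0.97 higher in polysomal than in total RNA. Across genes, the total RNA difference correlated with the polysomal minus total difference at r = 0.159. Whether the 5 genes reflect a difference between the total RNA preparations stays open.

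The lowest genes in total RNA of RBM35A+ cells did not reach 2-fold. CAMK2G, a calmodulin-dependent kinase, had a difference of −0.97, though another probe set gave 0.35 and a further one was at the floor. The Polycomb protein PHC2 was at −0.87, the lysosomal membrane protein SCARB2 at −0.77, the spindle-positioning protein MISP at −0.76, the nuclear receptor coactivator NCOA1 at −0.76 (other probe set at the floor) and the receptor-modifying protein RAMP1 at −0.75. The secreted phospholipase PLA2G2A was at −0.71 (other probe set −0.29) and the replication licensing factor CDC6 at −0.69. At 1.5-fold, 51 genes were higher and 22 lower, and 98% of the 3588 genes lay within 1.5-fold. The SD over genes was 0.223, against 0.185 for the disagreement of 1 probe set. The count of 5 became 3 with a floor of 6, 3 with the mean of each gene's probe sets and 3 with the fraction trend removed.

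Among gene lists, ribosomal protein transcripts were slightly lower in total RNA of RBM35A+ cells: the median of 46 members was −0.08 (percentile 0.04 of random lists), 35 members were below 0, and 0 passed 1.5-fold in either direction. RPS25 (−0.31), RPS15A (−0.25, other probe set −0.41) and FAU (−0.23) lay lowest. The proteasome list was also lower (25 members, median −0.11, percentile 0.91), with PSMA4 at −0.68 (other probe set −0.30), PSMB6 at −0.40 and PSMA3 at −0.37, 1 member lower at 1.5-fold and 0 higher. Wnt targets were lower (8 members, −0.19, percentile 0.44), with the stem cell factor ASCL2 at −0.64 and the ephrin receptor EPHB3 at −0.47, and with 1 member lower and 0 higher at 1.5-fold. So were immediate early genes (12 members, −0.14, percentile 1.45), with KLF10 at −0.35 (other probe set −0.15) and MCL1 at −0.34 (other probe set −0.07). Among the immediate early genes JUND went the other way at 0.32 (other probe sets 0.12 and 0.57), and 0 members passed 1.5-fold in either direction. The median of translation factors was slightly lower (28 members, −0.08, percentile 2.26), with EIF4B at −0.47, EIF4EBP1 at −0.46 and EIF1 at −0.42. Of these members 0 passed 1.5-fold in either direction. In polysomal RNA the ribosomal list (median −0.02, percentile 24.7), the proteasome (0.06, 89.6) and Wnt targets (−0.06, 14.6) lay inside the band. So did translation factors (−0.06, 4.52), while immediate early genes lay below it there too.

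Epithelial junction and keratin genes were higher in total RNA (26 members, median 0.10, percentile 99.2), with EVPL at 0.63 and JUP at 0.42 but CLDN3 at −0.44. Only 1 of them passed 1.5-fold, and the list lay at percentile 75.5 with the mean of each gene's probe sets and 77.1 without probe sets of shared sequence. In polysomal RNA its median was −0.05 (percentile 5.09), inside the band. The 3 analysed histone genes were H2BC15 (0.46), H2BC13 (0.28) and H2BC12 (0.12). Their median lay on the upper edge of the band and inside it under 6 of 7 alternatives. In polysomal RNA their median was −0.01 (percentile 23.9), inside the band. The positions of translation factors (percentiles up to 3.95), immediate early genes (3.82 with a floor of 4), Wnt targets (up to 3.76) and the proteasome (3.63 with the fraction trend removed) were also lost under some alternatives.

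In polysomal RNA, 0 genes were at least 2-fold higher and 6 were at least 2-fold lower in RBM35A+ cells. TMEM259, a membrane protein of the endoplasmic reticulum, was 3.13-fold lower (7.91 to 6.26) while its total RNA level was the same (9.72 on both arrays). The transcription factor MYC was 2.41-fold lower (8.04 to 6.77) with −0.21 in total RNA, and other probe sets gave −0.69 and −0.04, with a further one at the floor on both polysomal arrays. EIF2S3, the gamma subunit of the translation initiation factor eIF2, was 2.14-fold lower (6.83 to 5.73), with −0.98 at its other probe set and −0.06 in total RNA. CCDC85B was 2.12-fold lower, KLHDC3 at least 2.10-fold lower and the ubiquitin ligase RNF19B 2.01-fold lower. The gluconeogenic enzyme PCK1 (−0.93, other probe set at the floor) and EPHB3 (−0.93) followed.

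The highest genes in polysomal RNA were the metallothionein MT1G (0.96), the ubiquitin ligase MID1 (0.91), the pyruvate kinase PKM (0.84), the epithelial zinc-finger factor OVOL2 (0.83), the exchange factor ARHGEF7 (0.79), S100A2 (0.76, other probe set 0.16), the oligosaccharyltransferase STT3A (0.74) and the mitotic activator CDC20 (0.72). At 1.5-fold, 26 genes were higher and 44 lower, 98% of genes lay within 1.5-fold, and the SD over genes was 0.218 against 0.18 for 1 probe set. In RBM35A− cells the polysomal minus total difference of the 6 genes lower by 2-fold was between −0.83 for RNF19B and −4.61 for KLHDC3. Their count became 3 with a floor of 6 and 3 with the fraction trend removed, and the 5′ control probe sets of beta-actin and GAPDH differed between the polysomal arrays in the same direction.

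Transcripts of the ATF4 and amino acid response stood apart as lower in polysomal RNA of RBM35A+ cells: 16 of 19 members were below 0, the median was −0.16 (percentile 0.1), and DDIT4 (−0.73), CEBPB (−0.45), ATF4 (−0.44) and PYCR1 (−0.39) lay lowest, with 1 member lower and 0 higher at 1.5-fold. In total RNA the same list had a median of −0.01 (percentile 39). Immediate early genes were lower too (12 members, median −0.26, percentile 0.01), with MYC at −1.27, IER3 at −0.63, DUSP6 at −0.49 and ZFP36 at −0.46, and with 2 members lower and 0 higher at 1.5-fold. Nuclear-encoded respiratory chain transcripts were higher (46 members, median 0.11, percentile 100), 33 of them above 0, with UQCRC2 at 0.51, COX7A2 at 0.42 and SDHA at 0.42. None of them (0) was 1.5-fold higher, and 1, ATP5F1A at −0.80, was 1.5-fold lower. Mitosis genes were higher (25 members, 0.14, percentile 99.9), with CDC20 at 0.72 and PTTG1 at 0.40 but STMN1 at −0.40, and with 1 member higher and 0 lower at 1.5-fold. With a floor of 6 the mitosis list lay at percentile 96.4.

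Metallothioneins were higher in polysomal RNA (7 members, median 0.50, percentile 100), with MT1G at 0.96, MT1E at 0.52 and MT1H at 0.50, against a median of 0.11 (percentile 89.8) in total RNA. Their probe sets can share targets, so the members are not separate measurements. Beside all polysomal lists stands the lower 5′ signal of the RBM35A+ polysomal array (−0.86 for beta-actin). Respiratory chain, ATF4, immediate early and metallothionein lists stayed outside the band under every alternative run, removal of the fraction trend included. None of these alternatives tests 5′ loss, since the place of each probe set along its transcript was not used.

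**Figure D2:**
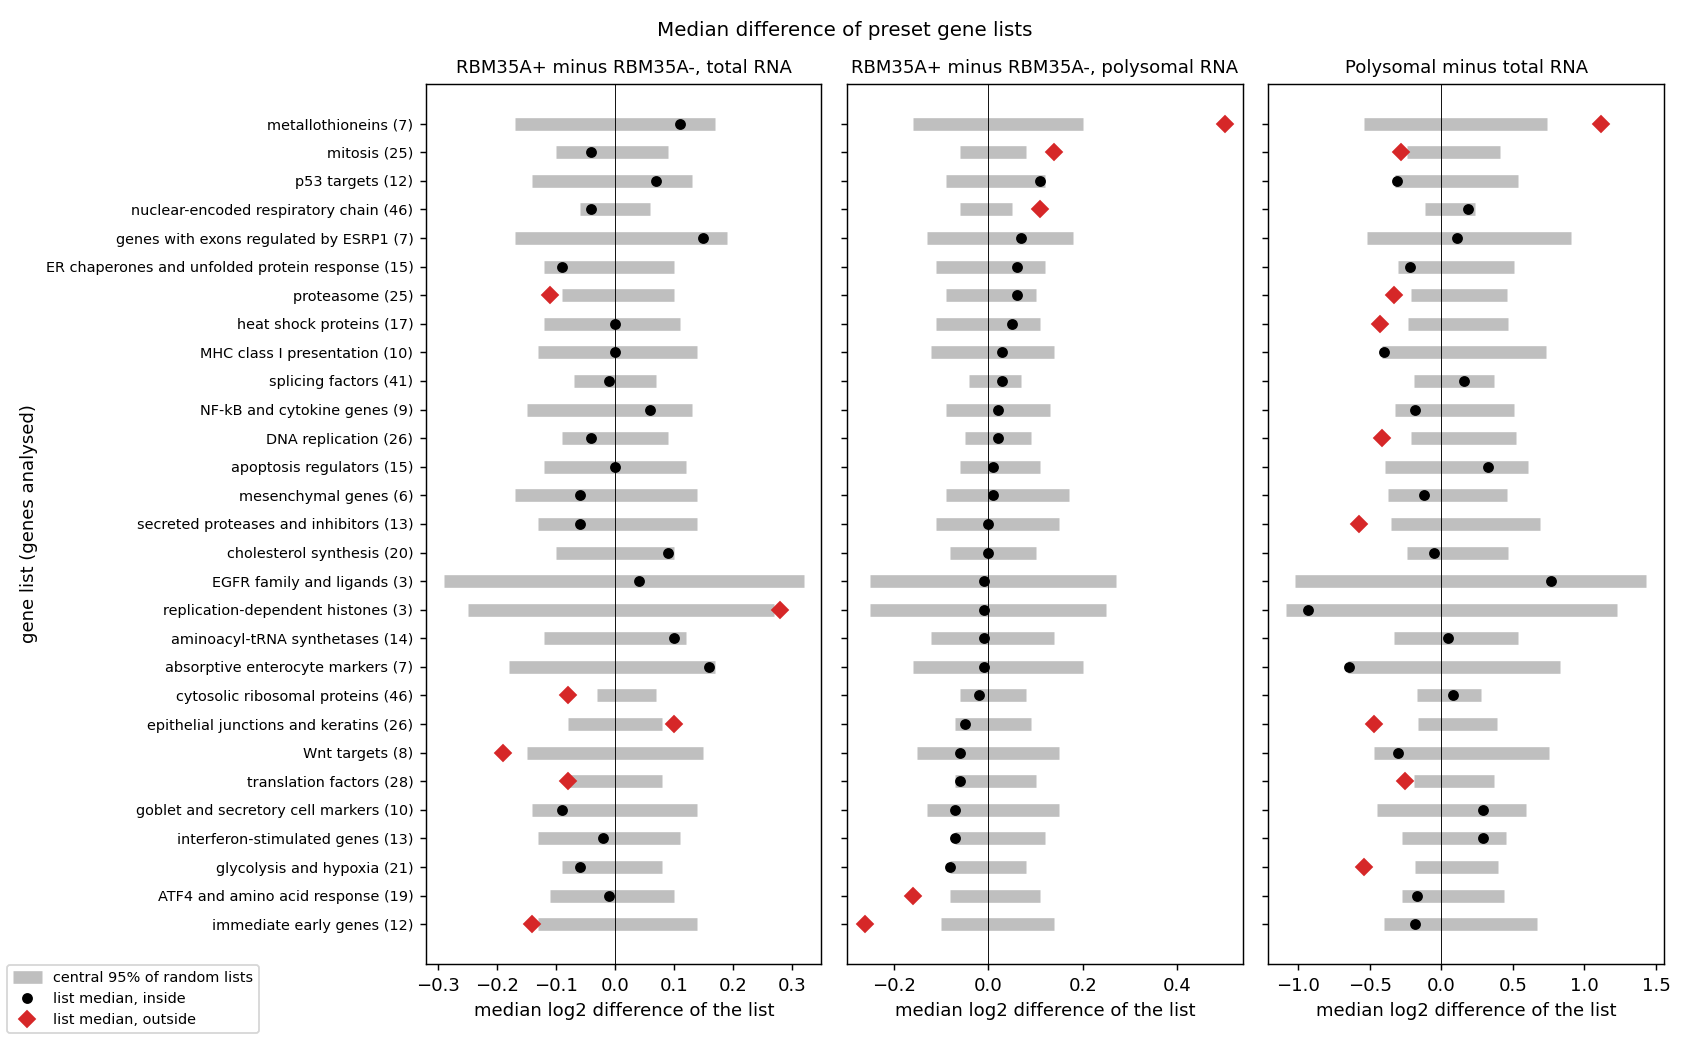
Median log2 difference (x axis) of each preset gene list with at least 3 analysed members (y axis, members in brackets) for RBM35A+ minus RBM35A− in total RNA, the same in polysomal RNA, and polysomal minus total RNA. Grey bars span the central 95% of 10000 random lists, black circles are medians inside them and red diamonds medians outside, such as the metallothioneins at 0.50 and immediate early genes at −0.26 in polysomal RNA.

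PKM was the 1 gene at least 1.5-fold higher in both fractions (0.68 in total, 0.84 in polysomal RNA), against 0.37 expected from the sizes of the gene sets. No gene (0) was 1.5-fold lower in both, with 0.27 expected, and 0 moved 1.5-fold in opposite directions. The 12 genes highest in both, ranked by the smaller of the 2 differences, began with PKM, and the rest fell short of 1.5-fold in at least 1 fraction. They were CYP3A5 (1.73 and 0.56), the lipid flippase ATP10B (0.63 and 0.54), the lysosomal protein LAMP1 (0.53 and 0.57), the coactivator NCOA2 (0.68 and 0.52), OVOL2 (0.52 and 0.83) and MALL (0.74 and 0.51). Next came ZMYM3 (0.54 and 0.51), the deubiquitinase OTUB1 (0.82 and 0.48), the matrix proteoglycan HSPG2 (0.47 and 0.62), the integrin ITGA3 (0.63 and 0.46, other probe set 0.27 and 0.11) and ZFHX3 (0.60 and 0.46). Genes lower in both included the endosomal GTPase RAB4A (−0.63 and −0.54; other probe sets −0.25 and −0.23, and −0.04 and 0.01), SMYD5 (−0.53 and −0.54), CCDC85B (−0.51 and −1.09), the autophagy protein MAP1LC3B (−0.52 and −0.50), TGDS (−0.63 and −0.48) and EPHB3 (−0.47 and −0.93). The translation repressor EIF4EBP1 (−0.46 and −0.49), the transcription factor CEBPB (−0.48 and −0.45), MISP (−0.76 and −0.44), DCTN6 (−0.43 and −0.52), FUBP3 (−0.43 and −0.57) and PHLDA1 (−0.42 and −0.66) completed the 12 lowest. Total RNA values of ZFHX3 and TGDS and the polysomal value of MISP include a floored array.

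Across genes, which are not independent replicates, the differences in total and polysomal RNA correlated with Pearson's r = 0.269 (bootstrap range 0.234 to 0.297) and Spearman's rho = 0.263, and 60% of 3082 genes had the same sign. In the additive model fitted with limma, 0 genes passed an adjusted p of 0.05 for RBM35A state, and the smallest adjusted p was 0.369. At an unadjusted p under 0.05 there were 369 genes (199 higher, 170 lower), against 179 expected. PKM had the smallest p (mean difference 0.76, SE 0.106, adjusted p = 0.369 with limma), and the mean differences of ATP10B, OVOL2, NCOA2 and MALL were 0.59, 0.68, 0.60 and 0.63. On the lower side were RAB4A (−0.58, with its other probe sets nearer 0), SMYD5 (−0.53), TGDS (−0.55), CCDC85B (−0.80) and EPHB3 (−0.70). Without the floor, limma called 6 genes higher and 9 lower.

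Adjusted over the list alone, limma called 5 gene and list pairs for RBM35A state, against 0 genes over all genes tested. CEBPB (−0.46) and DDIT4 (−0.55) of the ATF4 list had adjusted p = 0.036, EPHB3 (−0.70) of the Wnt list 0.015, PKM (0.76) of the glycolysis list 0.0061 and MT1G (0.67) of the metallothioneins 0.03. The other 25 lists had 0 such genes. Each list was adjusted by itself with no correction across lists, so some such calls would arise by chance.

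**Figure D3:**
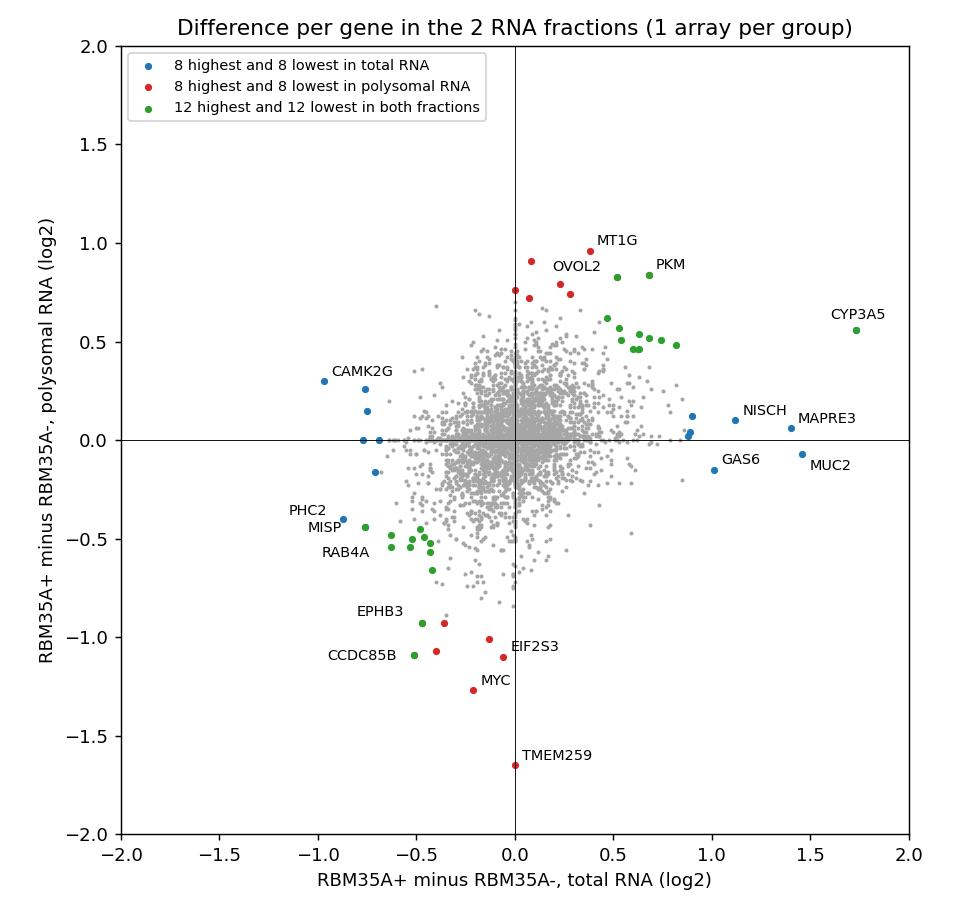
Log2 difference of RBM35A+ minus RBM35A− in total RNA (x axis) against polysomal RNA (y axis), 1 point per gene for the 3588 genes analysed, with the named genes coloured by the rule that named them. CYP3A5 lies at 1.73 and 0.56, MUC2 at 1.46 and −0.07, and TMEM259 at −1.65 on the y axis.

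The RBM35A difference was not the same in both fractions for several genes. MUC2 was 1.46 higher in total RNA and −0.07 in polysomal RNA, a difference of differences of −1.52, and another secreted mucin, MUC6, was at 0.85 and −0.20 (−1.06). TMEM259 (−1.64), MAPRE3 (−1.34), CYP3A5 (−1.17), GAS6 (−1.15), MYC (−1.06, other probe sets −0.33 and −0.11) and the spectrin SPTAN1 (−1.06) made up the rest of the 8 lowest. On the other side were CAMK2G (1.27), the galactose kinase GALK1 (1.09), NCOA1 (1.02), RAMP1 (0.91), the spliceosomal protein SNRPA (0.86), BTG3 (0.85), the decapping factor EDC4 (0.84) and the malic enzyme ME3 (0.83). In all, 3 genes were at 1 or more and 10 at −1 or less. No test was possible, and 1 probe set's SD for this quantity was 0.23. CAMK2G and GAS6 changed sign, to −0.21 and 0.18, without probe sets of shared sequence, and the count of 3 ranged from 1 to 6 over the floors.

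The median mitosis gene had a higher difference in polysomal than in total RNA (25 members, median 0.24, percentile 100), led by CDC20 (0.65), AURKA (0.45, other probe set 0.36) and KIF2C (0.43). TOP2A went the other way at −0.38 (other probe set −0.01, a further one at the floor in polysomal RNA). Of the mitosis members 18 were above 0 and 7 below, and 1 was higher and 0 lower at 1.5-fold. Respiratory chain genes (46 members, 0.13, percentile 100), the proteasome (25 members, 0.17, percentile 99.7), DNA replication (26 members, 0.16, percentile 99.4) and the metallothioneins (7 members, 0.39, percentile 100) also lay above the band, with COX7A2 at 0.69, PSMA4 at 0.53 (other probe set 0.27), TK1 at 0.59 (other probe set 0.01) and MT1F at 0.71. The respiratory chain gene ATP5F1A went the other way, at −0.62. At 1.5-fold, 2 respiratory chain members were higher and 1 lower, 2 replication members higher and 0 lower, and 1 metallothionein higher and 0 lower. The 2 replication members were TK1 and CDC6, and CDC6 (0.69) was at the floor in polysomal RNA. No proteasome member (0) passed in either direction. Epithelial junction and keratin genes lay below the band (26 members, −0.21, percentile 0), with JUP at −0.65, DSG2 at −0.60 and KRT19 at −0.34 but CLDN3 at 0.38. So did absorptive enterocyte markers (7 members, −0.25, percentile 0.75), with the fatty acid binding protein FABP1 at −0.57 and LGALS4 at −0.37, and the ATF4 list (19 members, −0.19, percentile 0.16). Of the epithelial members 8 were above 0 and 18 below, and 0 were higher and 2 lower at 1.5-fold. No enterocyte member (0) passed 1.5-fold. The ATF4 list had 0 members lower and 1 higher, PSPH at 0.64, which was at the floor in polysomal RNA. The enterocyte list lay inside the band with a floor of 6 (4.11) and without probe sets of shared sequence (2.62). The 5′ control probe sets of beta-actin and GAPDH differed by −0.86 and −0.79 in polysomal RNA, against −0.05 and −0.03 in total RNA.

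Polysomal minus total differences were alike in both cell states (r = 0.956 across genes). Both states share the extraction methods and the separate normalization of the fractions, so this agreement does not replicate the fraction difference. The calls that follow rest on that agreement, and 1 probe set's SD for the polysomal minus total difference was 0.706. With limma, 1383 genes were higher and 984 lower in polysomal RNA at an adjusted p of 0.05, 493 and 274 of them by at least 2-fold. Higher in polysomal RNA were THOC2 of the mRNA export complex (at least 35.1-fold, adjusted p = 5.92e-06, but 0.81 at its other probe set), GAS6 (4.63, other probe sets 1.95 and 2.69), NISCH (4.04), CAMTA2 (3.81), MCF2L (3.60), the adenylate cyclase ADCY6 (3.50), ADGRL1 (3.44), CDS1 (3.39, other probe set 1.68), the bicarbonate transporter SLC4A7 (3.34) and SUGP2 (3.28). Lower were KLHDC3 (−4.95), the chromatin protein RBBP4 (−4.69, other probe set −0.06), the interferon-induced kinase EIF2AK2 (−4.36, other probe set −0.20), the kinase PIM1 (−4.10, other probe set −1.99), ITM2B (−3.79), the ATP synthase subunit ATP5F1A (−3.77), CCNG1 (−3.47), SSR1 (−3.44, other probe set −1.65), ANXA2 (−3.05) and PSMD5 (8.00-fold lower). Values of THOC2, GAS6, CAMTA2, MCF2L, KLHDC3, RBBP4, EIF2AK2, ITM2B and ANXA2 include floored arrays and are lower bounds in size.

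The fractions had been normalized separately, which leaves the zero point between them open, and the labels name polyA RNA for the polysomal arrays alone. The median over genes was 0.09 as deposited and −0.08 after centring each array, a shift of 0.17. Of the calls, 58.4% were higher in polysomal RNA as deposited, against 44.5% after centring (993 higher, 1240 lower) and 51.8% after quantile normalization of all arrays (1210 higher, 1125 lower). The difference also varied along single transcripts, from −4.91 at the 5′ to −0.29 at the 3′ probe set of beta-actin.

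Relative to random lists, which share any shift of all genes, glycolysis and hypoxia genes were lower in polysomal RNA (21 members, median −0.54, percentile 0, limma 4 higher and 12 lower), with ALDOC at −1.96 and P4HA1 at −1.94. VEGFA went the other way at 1.74. Epithelial junction and keratin genes were lower (26 members, −0.47, percentile 0, 3 higher and 15 lower), with KRT19 at −1.39 and JUP at −1.33. EVPL (1.35) and ST14 (1.33) went the other way. DNA replication (26 members, −0.41, percentile 0.15, 7 higher and 15 lower) included RRM2 at −2.28 and MCM4 at −1.77, but also POLE at 2.95. The RRM2 and MCM4 values include floored arrays. Mitosis (25 members, −0.28, percentile 1.01, 2 higher and 12 lower) included CCNA2 at −1.67 (other probe set −1.08). Heat shock proteins (17 members, −0.43, percentile 0.26, 2 higher and 11 lower) included HSPA4 at −1.76 and DNAJB1 at −1.72. The proteasome (25 members, −0.33, percentile 0.32, 2 higher and 14 lower) included PSMA3 at −1.37. Translation factors (28 members, −0.25, percentile 0.77, 2 higher and 14 lower) included EIF2S3 at −2.55 and EIF4EBP1 at −2.32. Secreted proteases and inhibitors (13 members, −0.57, percentile 0.38, 3 higher and 7 lower) included CST3 at −1.55, but also SLPI at 1.27.

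All 7 metallothioneins analysed were higher in polysomal RNA (median 1.12, percentile 99.7), with MT1E at 1.47 and MT1B at 1.41. Ribosomal protein transcripts lay inside the band (median 0.08, percentile 62.7, limma 8 higher and 3 lower), and their median was −0.12 after centring and 0.01 after cyclic loess. Adjusted over the list alone, limma called 3 ribosomal protein genes higher and 1 lower, 4 glycolysis genes higher and 12 lower, 3 epithelial genes higher and 15 lower, 7 replication genes higher and 16 lower, 2 translation factors higher and 11 lower, and 7 metallothioneins higher. The mitosis list lay inside the band with the mean of each gene's probe sets (4.74) and without probe sets of shared sequence (3.18), and the secreted proteases with a floor of 6 (4.43).

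The other lists lay inside the band in every comparison with a floor of 5 and the values as deposited, and some left it under alternatives. Among 10 goblet and secretory cell markers (medians −0.09 in total and −0.07 in polysomal RNA), MUC2 (1.46) and FCGBP (0.75) were higher in total RNA while TFF1 was at −0.53. The 7 genes with exons regulated by ESRP1 had medians of 0.15 and 0.07, with NF2 at 0.26 and 0.53, though its other probe set was at −0.31 in total RNA and at the floor in polysomal RNA. Splicing factors (41 members) had −0.01 and 0.03, with HNRNPH1 at −0.77 and SNRPA at 0.66 in polysomal RNA. Mesenchymal genes (6 members) had −0.06 and 0.01, cholesterol synthesis (20) 0.09 and 0.00, ER chaperones and unfolded protein response (15) −0.09 and 0.06, and aminoacyl-tRNA synthetases (14) 0.10 and −0.01. Interferon-stimulated genes (13) had −0.02 and −0.07, p53 targets (12) 0.07 and 0.11, NF-kB and cytokine genes (9) 0.06 and 0.02, MHC class I presentation (10) 0.00 and 0.03, apoptosis regulators (15) 0.00 and 0.01, and the EGFR family (3) 0.04 and −0.01. In polysomal minus total RNA the p53 targets were at percentile 2.73, and between 2.28 and 2.42 under the 3 other scalings. Interferon-stimulated genes in polysomal RNA were at percentile 2.75, and at 1.44 with a floor of 4, 2.11 after centring and 1.48 with the fraction trend removed; in polysomal minus total RNA they were at 97.6 with the mean of each gene's probe sets. That setting also put the genes with exons regulated by ESRP1 at 1.46 in polysomal minus total RNA and the goblet markers at 1.83 in the difference of differences. MHC class I presentation was at 2.44 in polysomal minus total RNA without a floor. Glycolysis and hypoxia genes in polysomal RNA lay inside the band at percentile 3.00 and below it under 4 of 9 alternatives (0.11 to 1.92). Absorptive enterocyte markers lay inside it at 96.3 in total RNA and 2.92 in polysomal minus total RNA, and outside it under 4 of 9 alternatives in each.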

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

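Tests of 5′ loss, of a trend with expression level and of doxycycline were chosen after the results were seen. Among the 8 highest and 8 lowest differences of differences, genes whose RBM35A difference had opposite signs in the fractions, by more than the probe set error, were singled out. Genes outside that ranking could also have such opposite signs, for example JUP at 0.42 in total and −0.23 in polysomal RNA. The difference of these differences was not tested, as each group had 1 array.

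CAMK2G was at −0.97 in total and 0.30 in polysomal RNA (difference 1.27), but −0.21 without probe sets of shared sequence. NCOA1 was at −0.76 and 0.26 (1.02), GALK1 at −0.40 and 0.68 (1.09), and SNRPA at −0.20 and 0.66 (0.86). The other NCOA1 probe set gave −0.01 in polysomal RNA and was at the floor in total RNA. GALK1 lay near the floor, with values between 5.06 and 6.16. BTG3 was at −0.51 and 0.35 (0.85), EDC4 at −0.64 and 0.20 (0.84), and ME3 at −0.47 and 0.36 (0.83). In the other direction, SPTAN1 was at 0.59 and −0.47 (−1.06) and MUC6 at 0.85 and −0.20 (−1.06). A control probe set for the 5′ part of 18S ribosomal RNA, outside the comparisons, read 11.57 on the total RBM35A+ array and 2.22 on each of the other 3 arrays, while the 3′ probe set read 2.22 on all 4.

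The polysomal RBM35A+ array was lower than the polysomal RBM35A− array at the 5′ control probe sets of beta-actin (−0.865, against −0.02 at the 3′ end) and GAPDH. Whether this is 5′ loss of RNA in that preparation stays open at these transcripts, since they prompted the pattern and 0 other control transcripts lay above the floor at both ends. Such loss may account for part of the gene-level polysomal differences. The polysomal minus total difference was taken here as the RBM35A− polysomal array minus the mean of both total RNA arrays. Within the 358 genes with several measured probe sets, the probe set lower by this measure tended to have the lower RBM35A+ minus RBM35A− difference in polysomal RNA. The correlation was 0.278. For the total RNA difference, the correlation was −0.0733 with the polysomal minus total difference taken from the RBM35A+ total array. With that difference taken from the mean of both total RNA arrays it was 0.0575. No biological explanation for the 5′ pattern was tested, and how many of the 6 genes 2-fold lower in polysomal RNA (3 after the fraction trend was removed) reflect it stays open.

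RBM35A differences in total and polysomal RNA, from separate arrays, correlated across genes with r = 0.269. A trend with expression level as the whole cause is argued against by r within each of 10 groups of genes of like level, which was 0.204 at its lowest and 0.336 at its highest. A linear trend along the measured polysomal minus total difference is argued against as the whole cause by a partial r of 0.242. Its threshold was set before its value was seen, but removal of this trend as a setting was chosen after the data were seen. The total and polysomal RBM35A differences correlated with that difference at 0.159 and 0.228, and its probe set SD was 0.706. With correlations this low, r could fall only a little, and error in that difference weakens the test further. A shared axis of polysomal against total RNA that is not linear, or that varies along transcripts, was not tested. An effect of doxycycline, or of the cell line if the parental cells lacked the construct, cannot be told apart from one of RBM35A, because they changed together on all arrays; the ATF4 list, which doxycycline might be expected to move, lay at percentile 39 in total RNA and 0.1 in polysomal RNA. An effect of RBM35A thus remains open and untested against these.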

How the results depend on the processing

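No paired analysis was possible because each group had 1 array, so replicate numbers paired nothing; the additive limma model does set RBM35A+ against RBM35A− within each fraction, with 1 residual degree of freedom. No value existed for RBM35A itself under any setting, as no probe set was annotated to it. Over the settings chosen beforehand and the removal of the fraction trend, which was chosen after the data were seen, r between fractions stayed at 0.242 to 0.275. No gene (0) was 2-fold higher or lower in both fractions, or 2-fold higher in polysomal RNA, under any of them. Fraction calls ranged from 993 to 1604 higher and from 809 to 1240 lower. With a floor of 6, genes 2-fold higher in total RNA numbered 3 (5 before), 2-fold lower in polysomal RNA 3 (6 before), differences of at least 1 numbered 1 (3 before) and of at most −1 numbered 6 (10 before), since fewer values lie above that floor. With a floor of 4 and with none, 2 genes were 2-fold lower in total RNA (0 before) and 6 had a difference of at least 1. The mean of a gene's probe sets gave 3 genes 2-fold higher in total RNA and 1 with a difference of at least 1. Removing the fraction trend gave 3 higher and 1 lower in total RNA and 3 lower in polysomal RNA. Without a floor limma called 6 genes higher and 9 lower for RBM35A state, with a prior of 13.8 degrees of freedom against 5.33; under the other alternatives it called 0. Without probe sets of shared sequence, GAS6 turned to −0.25 and CAMK2G to 0.35 in total RNA, and their differences of differences to 0.18 and −0.21, because another probe set then stood for each gene. Of 1080 values of named genes under alternatives, 964 moved by less than the probe set error, 82 by more, 4 reversed and 30 could not be given. Of 29 list medians outside the band, 19 stayed outside under every alternative, and 70 of 87 inside stayed inside; causes were not tested. Signal over background limits most probe sets: 33.8% of them reached 5 on each total RNA array and 34.2% on each polysomal array.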

Other observations

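Tests on CD44, a cell adhesion receptor with exons known to be regulated by RBM35A, were chosen after its values were seen. Among 358 genes with at least 2 measured probe sets, CD44 ranked 2nd by how far 1 probe set departed from the others in the same direction in both fractions (0.65), after UBE3B (0.96).

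One CD44 probe set was higher in RBM35A+ cells by 0.60 in total RNA (7.59 to 8.19) and by 0.75 in polysomal RNA (5.74 to 6.49), while the medians of the 3 other CD44 probe sets above the floor in both fractions were −0.28 and 0.10; a further one was at −0.48 in total RNA and at the floor in polysomal RNA. Because CD44 was picked for that departure, neither the larger of those medians (0.1) nor the 0.6 in total RNA tests a change of the whole transcript or a differing 5′ loss. A change of exon use may account for the pattern, but cannot be told apart from these or from a probe effect: besides CD44 only 1 gene of the ESRP1 exon list had several measured probe sets, at percentile 33.3 of random gene sets. In that gene, the integrin ITGA6, 1 probe set was at −1.23 in polysomal RNA, with 0.12 in total RNA, while another was at −0.03 and a further one at −0.07 or lower, reaching the floor. Which exons the probe sets cover is not given in the sources used here.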
